A study of Arabidopsis thaliana with 8 samples.

How the data were processed

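GBF2 binding was measured by chromatin immunoprecipitation with an antibody against GFP in whole Arabidopsis seedlings that express GBF2 fused to Ypet, per the labels. The labels give 4 groups of 2 libraries each: immunoprecipitated chromatin and input, from DMSO-treated and from tunicamycin-treated seedlings. They do not say whether the 2 libraries of a group came from separate cultures.

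The submitters' processing notes name FastQC 0.11.5, cutadapt 1.8.1, Bowtie 1.1.2, SAMtools 1.8 and MACS2 2.1.2, and the genome build TAIR10. The role of each tool, its settings, the threshold for calling peaks, the use of the input libraries and the pooling of replicates are not given in the sources used here. The authors deposited 3 peak lists, with 1 list per treatment and 1 of tunicamycin-specific peaks, and no values per library. Each peak comes with a score that the authors deposited, called the signal value per the file headers. MACS2 writes a fold enrichment over the control into a field of that name, but the files do not say so, and the score was used only to describe, order, compare and filter peaks within a list. The width column that the authors deposited is the peak length in bp and equals end minus start plus 1 in all rows, so coordinates are 1-based. The files also give a position class for each peak (promoter of up to 1, 2 or 3 kb, UTR, exon, intron, downstream, distal intergenic) and 1 gene per peak, by a method not given in the sources used here. Depth per library is unknown, so a list can be longer because it was called from more reads, and no statement on signal per site is made across lists.

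From the deposited lists, peaks were called shared when they overlapped by at least 1 bp. The overlap was tested against 1000 random placements of the tunicamycin peaks on the same chromosomes (one-sided). Scores of shared and tunicamycin-only peaks were compared within a list by a two-sided permutation test of the difference of medians with 100000 resamples. Shares carry 95% Wilson intervals, which cover counting error only. A gene was called bound when the authors' files assigned it a peak of any class. Gene names, gene kinds and neighbours came from a RefSeq table of the assembly TAIR10.1. Its gene starts served to order genes into neighbours, and its coordinates were not set against peak positions. In it, 285 of 292 DMSO gene identifiers, 727 of 744 tunicamycin identifiers and 482 of 492 identifiers of the specific list matched. The 12 gene lists, with 141 members, were fixed before the data were examined, and each was tested against the other protein-coding nuclear genes of that table (27444 in all) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 36 tests and a threshold of 0.05. Tests of position class and gene kind were added after the data were examined.

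The design had foreseen gene assignment by peak summits from 1 kb upstream to 200 bp downstream of gene starts, and searches for the G-box, ER stress elements and 6-mers. These were not run, since no genome sequence or annotation of the build was used here and the files carry no summits. The authors' gene and class for each peak took their place, and peaks were not compared with random positions for their distance to genes.

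The genes named were fixed by rule before the data were examined: GBF2, list members with a peak in any list, list members without one where they are named as such, and the genes of the 10 strongest DMSO, tunicamycin and tunicamycin-only peaks. Genes named outside this rule in the closing observations were chosen after their values were seen, and the symbols KMD1 and KMD2 come from the table's synonyms. The gene list test was tested on simulated data: a list with 6 planted bound members among 622 bound of 27444 genes was called in 100 of 100 runs, and 1 of 1200 lists without planted members was called. Alternatives covered the overlap rule, the strongest 50% of each list, the position class, the background genes and protein-coding genes alone. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.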

Results

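GBF2 is a bZIP transcription factor of Arabidopsis thaliana that binds the G-box. Its binding sites were mapped by chromatin immunoprecipitation and sequencing in whole seedlings of the Columbia accession that carried GBF2 fused to the fluorescent protein Ypet under the GBF2 promoter, with an antibody against GFP. Seedlings 5 days old were kept for 6 h in 0.5 µg/mL tunicamycin, an inhibitor of N-glycosylation that brings on stress of the endoplasmic reticulum (ER), or in its solvent DMSO. There were 2 immunoprecipitated and 2 input libraries per treatment, 8 libraries in all. The values analysed are 3 peak lists, with 1 list for DMSO, 1 for tunicamycin and 1 of peaks that the authors set apart as specific to tunicamycin. No list gives values per library, so the sequencing depth and the spread between replicates are unknown, and the tests below treat peaks and genes, not seedlings, as the units.

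Where GBF2 bound with and without tunicamycin was compared first. The DMSO list held 320 peaks assigned to 292 genes, and the tunicamycin list held 767 peaks assigned to 744 genes. The strongest sites were largely the same in both: 8 genes stood among the 10 highest-scoring peaks of each list. The gene of another G-box factor, GBF3 (AT2G46270), had the highest score of the DMSO list, 8.75, at chromosome 2, 18998302 to 19000971 (TAIR10 coordinates throughout). The tunicamycin list placed it at rank 2 with a score of 7.25. CYP86A8 (AT2G45970), a cytochrome P450 of fatty acid hydroxylation, led the tunicamycin list with a score of 7.49, at chromosome 2, 18912017 to 18914383. The score is the authors' value for each peak and orders peaks within a list only.

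The CYP86A family, whose enzymes hydroxylate fatty acids for cutin and related polymers, took 4 of the 10 strongest tunicamycin peaks and 2 of the 10 strongest DMSO peaks, where CYP86A2 and CYP86A7 followed at ranks 11 and 12. In the tunicamycin list CYP86A8 lay with CYP86A4 (score 6.57), CYP86A2 (5.82) and CYP86A7 (5.72). These 4 of the 5 genes with CYP86A symbols had peaks in both lists. By the authors' classes, the tunicamycin peak of CYP86A7 was in the promoter class of up to 1 kb. That of CYP86A8 was in the 5′ UTR class, and those of CYP86A4 and CYP86A2 were in the exon class. The overlapping DMSO peak of CYP86A2 was in the promoter class of up to 1 kb, and that of CYP86A4 in the 3′ UTR class. The class thus differed between lists for overlapping peaks. A pair of genes for Kelch-repeat F-box proteins of the KISS ME DEADLY group, AT1G80440 (KMD1) and AT1G15670 (KMD2), stood among the 10 strongest peaks of each list, with tunicamycin scores of 6.56 and 5.58. HSP60-3A, which codes for a chaperonin, AT3G03790 and the pseudogene AT1G42420 were the other genes found among the 10 strongest of both. F8H, a homologue of the glycosyltransferase gene FRA8, reached the 10 strongest only in the DMSO list, with a score of 5.58.

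Of the 767 tunicamycin peaks, 277 overlapped a DMSO peak by at least 1 bp, which is 36.1% (95% Wilson interval 32.8 to 39.6%, which covers counting error only). From the other side, 272 of the 320 DMSO peaks (85%, 80.7 to 88.5%) overlapped a tunicamycin peak. Random placements of the tunicamycin peaks on their chromosomes gave a mean of 4.42 overlaps and at most 13 in 1000 placements (one-sided permutation test, p = 0.001, the smallest these placements can give). The placements were uniform along each chromosome and did not keep peaks at promoters, where most of them lay. The test therefore shows only more overlap than uniformly scattered peaks would give. Without an overlap were 490 peaks of the tunicamycin list and 48 of the DMSO list. The lists differ in length, and of the 320 strongest tunicamycin peaks 205 overlapped a DMSO peak, or 64.1% (58.7 to 69.1%).

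Overlap with the DMSO list was most frequent among the strong peaks. Among the 50 strongest tunicamycin peaks 49 overlapped a DMSO peak, and among the 100 strongest 91 did. Across 10 bins of the list ordered by score, the share was 97.4% in the strongest bin and 10.5% in the weakest. Within the tunicamycin list the 277 shared peaks had a median score of 2.81 (lower quartile 2.52) and the 490 tunicamycin-only peaks 2.35 (upper quartile 2.53), a difference of 0.454 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The highest score of a tunicamycin-only peak was 3.51.

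**Figure D1:**
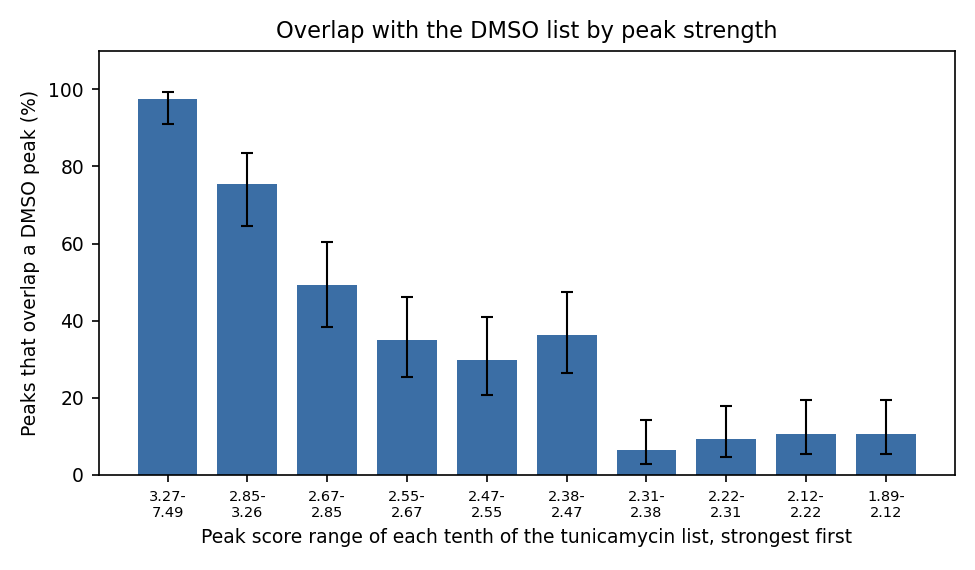
Share of tunicamycin peaks that overlap a DMSO peak by at least 1 bp (y axis, percent), in 10 bins of the tunicamycin list from the highest peak scores (left) to the lowest (x axis, score range of each bin). Bars are shares and whiskers are 95% Wilson intervals for counting error; the share falls from 97.4% to 10.5%.

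The strongest peaks found only under tunicamycin lay at genes of varied function. The leading ones were AT3G05260 (score 3.51, chromosome 3, 1498679 to 1499473), the expansin gene EXPA16 (3.28, chromosome 3, 20576739 to 20577662), SDG14, a SET-domain gene also named ATX3 (3.23), and TBP1, the gene of a telomeric DNA-binding protein (3.22). AT3G15548, AT4G16640, AT3G46320, the long non-coding RNA gene AT4G37895, AT4G16660 and AT1G01240 followed, with scores from 3.22 down to 3.10. Of these 10 peaks, AT3G05260 ranked highest in the whole tunicamycin list, at place 44.

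The authors' own list of tunicamycin-specific peaks held 502 peaks, all of them present in the tunicamycin list. Of these, 473 did not overlap a DMSO peak and 29 did. The 29 had a median score of 3.30 (range 2.11 to 5.82), and in 28 of them the overlapping DMSO peak was assigned to the same gene. CYP86A2, HSP60-3A and F8H were among them, as was GBF2 itself. The 17 peaks without a DMSO overlap that the specific list left out were all classed as distal intergenic, a class with 0 peaks in the specific list.

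The peak at GBF2 (AT4G01120) covered 6193 bp in the tunicamycin list, at chromosome 4, 482356 to 488548, with a score of 4.52 at rank 14. In the DMSO list this stretch was part of a peak of 13432 bp, chromosome 4, 474962 to 488393 (score 6.29), which the authors' assignment gave to ADNT1, a gene for a mitochondrial adenine nucleotide carrier. The transgene carries the promoter and coding sequence of GBF2, so reads from it fall on this locus too.

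Peaks lay mostly at promoters. By the authors' classes, 221 of 320 DMSO peaks (69.1%, 63.8 to 73.9%) and 583 of 767 tunicamycin peaks (76.0%, 72.9 to 78.9%) were in the promoter class of up to 1 kb. Distal intergenic peaks made up 11.3% of the DMSO list and 5.35% of the tunicamycin list. Within the tunicamycin list, promoter peaks of up to 1 kb were more frequent among tunicamycin-only peaks (79.2%) than among shared peaks (70.4%, adjusted p = 0.0102, Fisher's exact test, two-sided, adjusted over 10 tests of class and gene kind that were chosen after the peaks were examined). In the DMSO list the direction was the opposite, with 54.2% of DMSO-only and 71.7% of shared peaks (exact adjusted p = 0.0203). Distal intergenic peaks made up 33.3% of DMSO-only and 7.35% of shared DMSO peaks (exact adjusted p = 2.45e-05), and 3.47% of tunicamycin-only and 8.66% of shared tunicamycin peaks (adjusted p = 0.00782). Most of the DMSO-only ones were assigned to pseudogenes and lay close together on chromosomes 3 and 4. They lie outside the promoter class, so they also lower its share among DMSO-only peaks. Both DMSO tests count them as independent sites, which they are not, and the promoter share without them was not tested. In the 3′ UTR class the shares were 6.12% of tunicamycin-only and 1.81% of shared peaks (exact adjusted p = 0.00902), while in the DMSO list 0 of 48 DMSO-only and 11 of 272 shared peaks were in it (adjusted p = 0.381).

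The genes beside the peaks differed in kind between shared and unshared peaks. Transfer RNA genes took 50 of the 490 tunicamycin-only peaks (10.2%) and 12 of the 277 shared ones (4.33%, exact adjusted p = 0.00782). In the DMSO list they took 8 of 48 DMSO-only peaks (16.7%) and 13 of 272 shared peaks (4.78%, exact adjusted p = 0.00902). Within the tunicamycin list, peaks at tRNA genes scored lower than those at protein-coding genes (median 2.33 against 2.48, two-sided permutation test, p = 0.00365). Weak peaks were less often shared, so the tRNA excess was not separated from peak strength. Pseudogenes were rarer among tunicamycin-only peaks, 2.24% against 11.6% of shared peaks (exact adjusted p = 2.20e-06). Of the DMSO-only peaks 37.5% were assigned to pseudogenes, against 10.7% of shared DMSO peaks (exact adjusted p = 4.71e-05). Most of these DMSO-only peaks were classed as distal intergenic, so this result and that of the distal class rest largely on the same peaks. In the DMSO list several shared peaks at pseudogenes also lay next to each other. The pseudogene tests of both lists count peaks as independent, so their p-values can overstate the evidence.

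**Figure D2:**
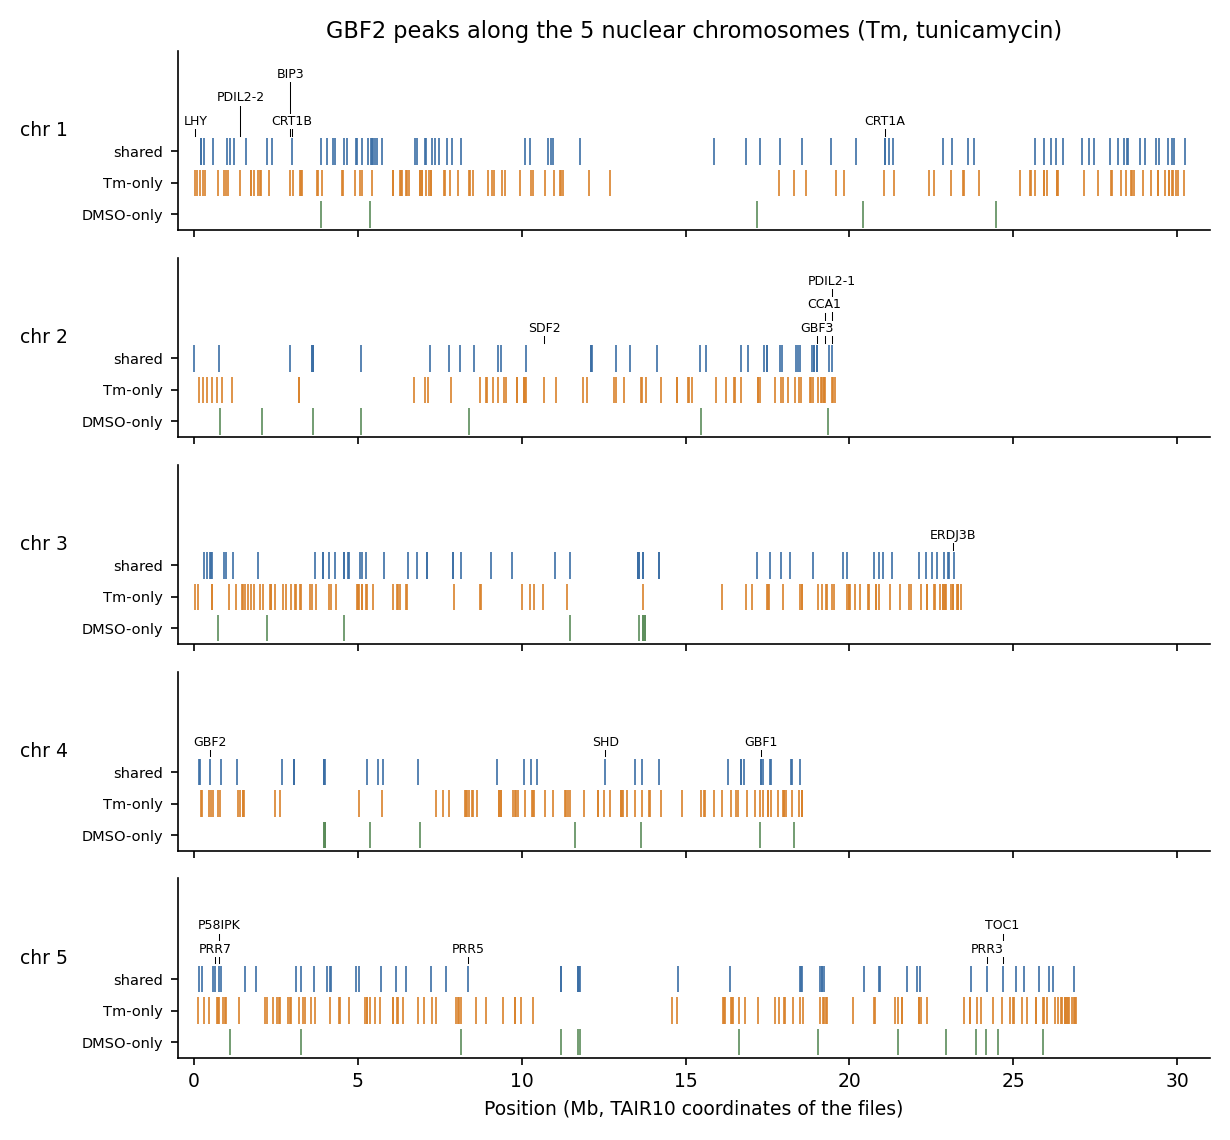
Positions of GBF2 peaks on the 5 nuclear chromosomes (x axis, Mb; Tm, tunicamycin). Each vertical line is a peak midpoint, in the upper row of a chromosome the 277 tunicamycin peaks that overlap a DMSO peak, in the middle row the 490 tunicamycin-only peaks and in the lower row the 48 DMSO-only peaks; names mark bound genes of the ER chaperone, clock and G-box factor lists at their tunicamycin peaks. DMSO-only peaks lie close together near 13 to 14 Mb on chromosome 3 and 3 to 4 Mb on chromosome 4.

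The same comparison was made by gene. Among 27444 protein-coding nuclear genes, 233 had a peak in the DMSO list and 622 in the tunicamycin list. Both lists shared 209 genes, where 5.28 would be expected of independent lists of these sizes; the one-sided Fisher's exact p was too small to be represented as a number. A further 413 genes had a peak in the tunicamycin list alone and 24 in the DMSO list alone.

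Genes of the unfolded protein response were examined next, since tunicamycin brings that response on. Chaperones and folding enzymes of the ER carried GBF2 peaks far more often than other genes, in both lists. In the tunicamycin list 9 of 24 had a peak (37.5%, 21.2 to 57.3%), against 2.24% of other protein-coding genes (odds ratio 26.2, adjusted p = 5.18e-08, Fisher's exact test, two-sided, adjusted over 12 gene lists in 3 peak sets). In the DMSO list 4 of 24 had a peak, against 0.835% of other genes (odds ratio 23.7, exact adjusted p = 0.000242). The 4 genes with peaks in both lists were the calreticulin genes CRT1A and CRT1B, SHD, the HSP90 of the ER, and P58IPK, a co-chaperone gene. CRT1A had the highest tunicamycin score of the group, 3.43, at chromosome 1, 21092291 to 21093508, and SHD had 3.39.

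A further 5 of these genes had tunicamycin-only peaks: the HSP70 gene BIP3 (score 2.37, chromosome 1, 2931285 to 2932756), the co-chaperone gene ERDJ3B (2.67), SDF2 (2.12), and the protein disulfide isomerase genes PDIL2-1 (2.35) and PDIL2-2 (2.38). All 9 peaks were in the promoter class of up to 1 kb. The list made up 5 of the 408 genes with tunicamycin-only peaks and 4 of the other 214 genes of the tunicamycin list, a difference that did not pass the test (Fisher's exact test, p = 0.503, adjusted p = 0.731 over 12 lists). Of these 5 genes, ERDJ3B alone lay in the strongest 50% of the tunicamycin list, where the tunicamycin-only set no longer passed (exact adjusted p = 0.275).

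The list of sensors and transcription factors of the response did not pass the test. Of 13 genes, NAC089 alone had a peak, in the tunicamycin list (score 2.51), which is 7.69% of the list (1.37 to 33.3%, odds ratio 3.60, exact adjusted p = 0.403). The difference between this list and the chaperone list was not tested. The genes bZIP60, bZIP28, bZIP17, IRE1A and IRE1B had no peak. Among 13 genes of ER-associated degradation and ER transport, SAR1B, a GTPase gene of vesicle export, had a peak in both lists (tunicamycin list exact adjusted p = 0.403). SAR1B and CRT1A are neighbouring genes in the TAIR10.1 table, each with a peak of its own. BIP1, BIP2 and CNX1 were among the 15 ER chaperone genes without a peak.

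The tunicamycin list, with 622 bound protein-coding genes against 233 in the DMSO list, held peaks at 7 of 23 genes of abscisic acid signalling and response (30.4%, 15.6 to 50.9%, odds ratio 19.1, exact adjusted p = 6.37e-06). The DMSO list held 1, the dehydrin gene ERD10 (exact adjusted p = 0.321). Tunicamycin-only peaks lay at the protein phosphatase 2C genes PP2CA (score 2.14), HAI1 (2.61) and HAI2 (2.63), the dehydrin gene COR47 (2.61), the cold-induced gene KIN2 (2.24) and ADH1, an alcohol dehydrogenase gene (2.53), with an adjusted p of 7.63e-06 for these 6. Their share of the tunicamycin-only genes, 6 of 408, did not differ from the 1 of 214 among the other genes by the test (exact p = 0.432, adjusted p = 0.731). No gene of the ABI or ABF series on the list had a peak.

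Clock genes were bound in both lists. Of 14 genes 6 had a tunicamycin peak (42.9%, 21.4 to 67.4%, odds ratio 32.6, exact adjusted p = 6.13e-06) and 4 a DMSO peak (28.6%, adjusted p = 3.41e-05). The 4 were TOC1, PRR3, PRR5 and PRR7, all of the pseudo-response regulator family. PRR7 scored highest, 4.42 in the tunicamycin list (rank 15, chromosome 5, 641728 to 642835) and 5.18 in the DMSO list (rank 16). CCA1 (2.14) and LHY (1.99), the morning MYB genes, had tunicamycin-only peaks with low scores, and the list missed the threshold among tunicamycin-only peaks (2 of 14, exact adjusted p = 0.0535). In the DMSO list the call rested on weak peaks, since with the strongest 50% of the list 1 member was left (exact adjusted p = 0.181).

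Among the G-box factor genes, GBF3, GBF1 (tunicamycin score 3.65) and GBF2 of 7 listed genes had tunicamycin peaks (exact adjusted p = 0.0017), and GBF3 and GBF1 had DMSO peaks (adjusted p = 0.00586). Without GBF2, whose locus also takes reads from the transgene, 2 of 6 had a tunicamycin peak (exact adjusted p = 0.0236). None of the 7 had a tunicamycin-only peak, and bZIP16, bZIP68, HY5 and HYH had no peak. Genes of sugar starvation and amino acid breakdown had tunicamycin-only peaks at 2 of 6 members, DIN10 and MCCA (exact adjusted p = 0.0114). Both scores were 2.26 to 2.27, and the strongest 50% of the list held 0 of the 6. No other list passed: CAT2 of 8 photosynthesis genes, YUC8 of 10 shade-response genes and HSP101 of 5 heat shock genes had peaks in both lists. None of the 7 flavonoid genes or the 11 reference genes, such as ACT2 and UBQ10, had a peak, with upper Wilson limits of 35.4% and 25.9% in the tunicamycin list. Since the files give 1 gene per peak, a gene counted as unbound can lie next to a peak given to its neighbour: in the TAIR10.1 table MYB12 of the flavonoid list neighbours PDIL2-1 and KIN1 neighbours KIN2, and HRD3A, DER2.2, UBC32, PRR9, LUX, PIF5 and BCAT2 also have a bound neighbour.

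**Figure D3:**
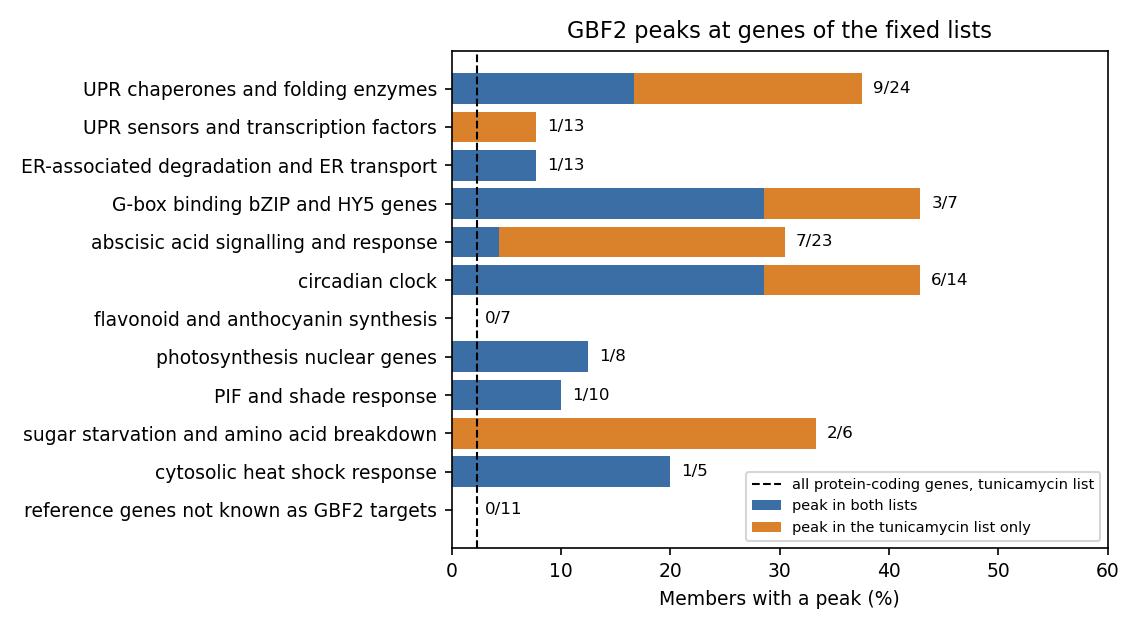
Share of the members of each of 12 gene lists that had a GBF2 peak (x axis, percent of members; the counts of bound and listed genes stand beside the bars). Blue marks genes assigned a peak in both lists, orange those assigned one in the tunicamycin list alone, and the dashed line the share of all protein-coding genes in the tunicamycin list; GBF2 counts as orange because the DMSO peak over it was assigned to ADNT1.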

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

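The comparisons by promoter class, by gene background, by protein-coding genes alone, with the authors' specific list in place of tunicamycin-only peaks, by the 50% and 200 bp overlap rules for gene lists and the specific list, and with the strongest 50% of the tunicamycin list against all DMSO peaks were chosen after the data were examined. With the strongest 50% of each list, 134 tunicamycin peaks were shared and 105 genes had a peak in both lists, fewer because fewer peaks enter; the DMSO promoter share was 62.5%; ER chaperone genes among tunicamycin-only peaks came to 2 (ERDJ3B, and P58IPK, whose DMSO peak was left out; exact adjusted p = 0.0592); and sugar starvation genes came to 0 both in the tunicamycin list and among tunicamycin-only peaks, where weak peaks had given 2. With the strongest 50% of the tunicamycin list against all DMSO peaks, ER chaperone genes came to 1 (exact adjusted p = 0.275), sugar starvation genes to 0 in both sets, and 1 list, abscisic acid genes, still passed among tunicamycin-only peaks, where 3 had. Midpoints within 200 bp put 55% of the 320 strongest tunicamycin peaks at a DMSO peak. All peaks were at least 310 bp long, so peaks with midpoints this close always overlap, and this rule is stricter by construction. Promoter classes of up to 2 and 3 kb, wider by construction, held 75.6% and 79.1% of DMSO peaks and 82.1% and 84.1% of tunicamycin peaks. Of the 11 calls of gene lists, 7 were kept with the strongest 50% of each list, 8 with that of the tunicamycin list alone and all 11 under each of the 5 other settings. Clock genes among tunicamycin-only peaks (exact adjusted p = 0.0535) passed as 1 new call under 4 settings: promoter classes of up to 1 kb (0.0339) and 2 kb (0.0391), all nuclear genes as background (0.0381), and the strongest 50% of each list (0.00081), where the 3 genes were TOC1, PRR3 and PRR5, whose DMSO peaks were left out. No paired analysis was possible because the peak lists give no values per library, and for that reason no replicate could be left out. Planned searches for the G-box, with their windows and backgrounds, the gene windows of 500 bp and the nearest gene start were not run, since no genome of the build was used and the files give 1 gene per peak and no summits. The unknown depth limits what the 490 and 48 unshared peaks show.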

Other observations

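All tests in this part were chosen after the peaks had been examined, and genes outside the fixed lists were picked with their values known.

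Some genes of iron handling had strong peaks. Tunicamycin peaks lay at OPT3, a phloem transporter gene (score 4.78, rank 13, chromosome 4, 9249939 to 9251086), the ferric reductase genes FRO2 (4.19, rank 20) and FRO3 (3.43), and the ferritin gene FER1 (3.34), and these 4 also had DMSO peaks. The regulator gene PYE had a peak in both lists (2.95), and BTS (2.34, rank 512), FER3 (2.64, rank 244) and NRAMP3 (2.35, rank 496) had one in the tunicamycin list alone. Of 25 iron genes listed once OPT3, FER1, FRO2 and members of the FER, FRO and NRAMP families had been seen, 8 had a tunicamycin peak (32%, odds ratio 20.5), a count that holds the genes that prompted the list. The 15 members outside those families leave out the genes that prompted the list. The hypothesis was that GBF2 sites may be more frequent at iron genes. The list was written after the peaks had been examined, so these members are not an independent test of it. In the tunicamycin list 2 had a peak, PYE and BTS (p = 0.0443, Fisher's exact test, two-sided). The adjusted p was 0.0591 over 4 tests, eased by the small p-values of the tests of all 25 genes among them. In the DMSO list 1 of the 15 had a peak (exact p = 0.12), so the hypothesis stays open. IRT1, FIT and the 4 NAS genes had no peak.

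Among 600 gene families formed by shared symbol stems of at least 4 genes, 5 had more tunicamycin peaks than other genes after adjustment. CYP86A led with 4 of 5 genes (adjusted p = 0.00077, Fisher's exact test, two-sided), followed by ERD with 4 of 12 (ERD2, ERD10, ERD14 and ERD15, adjusted p = 0.0224) and GBF with 3 of 5 (adjusted p = 0.0224). The GBF call rests on GBF2, whose locus also takes reads from the transgene: without it, 2 of 4 genes had a peak (exact adjusted p = 0.199), and the 4 other families still passed. ERF had 5 of 25 (ERF4, ERF5, ERF8, ERF12 and ERF15) and the PRR genes 3 of 6, each with an adjusted p of 0.0264. The ERD symbols name dehydration-induced genes of several protein families together with ERD2, a receptor gene of ER retention, so that stem is not a family by descent. Light-harvesting LHCB genes, with 3 of 9, did not pass (exact adjusted p = 0.0879).

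The tunicamycin list had 490 peaks without a DMSO peak. A stricter threshold or less depth for the DMSO list is a candidate explanation. Of the 50 strongest tunicamycin peaks 1 lacked a DMSO peak, but weak sites gained under tunicamycin would give such a count too, so it does not favour depth. New binding brought on by tunicamycin may also account for them. Its test was a larger share of ER chaperone genes among tunicamycin-only than among other bound genes. The share was smaller, 1.23% against 1.87% (odds ratio 0.651, Fisher's exact p = 0.503), but 5 and 4 members are too few to decide. These explanations cannot be told apart without values per library.

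Transfer RNA genes carried a tunicamycin peak in 62 of 625 cases (9.92%, 7.82 to 12.5%), 4.38 times the share of protein-coding genes, and in 21 cases a DMSO peak (3.36%). Repeated clusters are argued against, since 6.45% of the tRNA peaks lay within 50 kb of another. A one-way gain under tunicamycin was examined by the DMSO-only peaks, of which 16.7% lay at tRNA genes, above the 4.78% of shared DMSO peaks. In both lists tRNA peaks had a lower median score than peaks at protein-coding genes, and unshared peaks a lower one than shared peaks. Weak peaks missed in the other list would give this excess with or without a gain, so the shares cannot decide. Recovery of strongly transcribed genes without GBF2 stays open: the share of tRNA peaks did not differ by the test between the lists (6.56% and 8.08%, exact p = 0.453), and no control antibody or untagged line was analysed here. Assignment of a neighbouring promoter's peak to a tRNA gene also stays open, because distances to gene starts were not measured.

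Pseudogenes were the assigned genes of 18 of the 48 DMSO-only peaks, and most of the 18 were classed as distal intergenic. Of these 18 peaks, 17 had another DMSO peak within 50 kb, against 9 of 22 DMSO-only peaks at protein-coding genes (p = 0.000593, Fisher's exact test, two-sided). The p-value treats peaks as independent, but close peaks count each other, so it overstates the evidence. The peaks gathered in a few stretches, such as 13 to 14 Mb on chromosome 3 and 3 to 4 Mb on chromosome 4 with 5 peaks each. An origin in repeats stays open, since repeat content was not measured. A tunicamycin peak lay within 50 kb of 94.4% of the 18 peaks, so the lists do not show a loss of peaks from whole stretches. Close peaks share neighbours, so the 18 are fewer independent cases, and the share for random positions was not measured. A loss of binding is therefore not excluded. Whether single sites within the stretches differ was not tested.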
